A study of Homo sapiens with 4 samples.

How the data were processed

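RNA was measured on 4 Affymetrix Human Gene 1.0 ST arrays, 2 from embryoid bodies given DMSO and 2 from embryoid bodies given TBBD. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled by the array maker's standard procedure. Per the submitters' processing notes, the authors processed the arrays with RMA. The RMA version and its settings are not given in the sources used here. The deposited values are RMA signals on a log2 scale, 1 per exon-level probeset (a small group of probes within an exon) and array. The log2 scale was read from the values, whose maximum was between 13.7 and 13.8 on every array. No detection call or background estimate was used here, so it is unknown which genes lay above background, and the precision is limited by the number of arrays.

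The deposited table held 247312 probesets. A placeholder value far below any signal filled 358 cells, and the 277 probesets with such a cell were left out, which left 247035. Of all probesets, 219181 carried 1 gene symbol in the platform annotation, 9980 carried several and 18151 carried none. Probesets with several symbols or none stayed out of the gene values. The annotation held 18683 symbols on probesets with 1 symbol. Of these, 16056 were current, 2528 were updated through a RefSeq gene table of a human assembly, and 99 were kept as given. Coordinates of that table were not used, since the build behind the array design is not given in the sources used here. The log2 values of the 218927 named probesets were averaged per gene and array, which gave 18640 genes with a median of 9 probesets. The annotation placed 1068 genes on 1 probeset.

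Groups and replicate numbers were taken from the sample titles. TBBD was compared with DMSO by limma's moderated test on the log2 values with the group as the only term, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A relaxed count of genes at an unadjusted p under 0.05 and a fold of at least 1.5 described the size of the difference and made no correction for the number of genes. Of 52 gene lists written before the data were examined, 51 had at least 5 measured members and were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. The list of mitochondrially encoded transcripts had too few measured members. Changes in the 2 same-number differences, TBBD 1 minus DMSO 1 and TBBD 2 minus DMSO 2, were correlated across genes. Analyses used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

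The genes named were chosen by a rule also fixed before the data were examined. It took 16 genes of prior interest in every case. It took up to 12 genes per direction with the largest fold among those past the adjusted threshold whose TBBD arrays both lay on 1 side of both DMSO arrays. Where fewer than 6 passed, it took them from genes at an unadjusted p under 0.05, with the same separation and a fold of at least 1.5. It passed over unnamed loci, open reading frames, pseudogenes, clones and sex-linked genes used to tell samples apart. It also took the 3 members with the smallest p, in the list's direction, of each list past the threshold. Genes named in the closing part for other lists and for the replicate numbers, and 3 of the genes marked in the plot of same-number differences, were chosen after their values were seen.

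The fit was tested on simulated arrays with the measured gene means, run on 18640 genes with 2 arrays a group. It recovered 32.8% of 67 genes changed 2-fold, 95.5% of 67 changed 4-fold and 97.0% of 66 changed 8-fold. It called 12 of 18422 unchanged genes. Variances were drawn from the distribution that limma fitted, and noise was independent between arrays, with no difference between replicate numbers. The measured arrays did differ by number, so these shares need not hold for them. Alternatives were quantile normalization again, median centring, leaving out dim genes to keep the brightest 12426 or 9320, the median over probesets, genes with at least 3 probesets, an intensity trend, a robust prior, the replicate number as a block, each array left out, single probesets, other thresholds, an estimated correlation, ranks, and fry. Setting the placeholder cells to 0, and the alternative settings of the correlation of the same-number differences, were added after seeing the data.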

Results

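Gene expression was profiled in embryoid bodies, aggregates in which human embryonic stem cells begin to differentiate, grown from BG01V, a human embryonic stem cell line with a variant karyotype. The series asked how expression responds to TBBD, described in its title as an inhibitor of methylation at arginine 17 of histone H3. TBBD is another name for ellagic acid, and the methyltransferase CARM1 places this mark. The embryoid bodies received 10 µM TBBD or the vehicle DMSO for 48 h, generally between day 2 and day 4 of their formation. Each group held 2 arrays, named here replicate 1 and replicate 2. Median log2 signals of the probesets lay between 6.39 and 6.42 on the 4 arrays. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these samples, whose source the labels do not give.

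No single gene passed the test for a difference between TBBD and DMSO. The largest differences in either direction were a log2 value of 0.91 ± 0.12 (SE) for POTEC, a member of a primate ankyrin-repeat family, and -1.03 ± 0.20 for PALM2AKAP2, which encodes an anchoring protein for protein kinase A. Among genes measured on at least 3 probesets, LOX, which encodes the collagen cross-linking enzyme lysyl oxidase, was higher with TBBD by 0.67 ± 0.18 on the log2 scale. FEZF2, a transcription factor of the forebrain, was lower at -0.66 ± 0.12, the kinase gene PIM2 at -0.65 ± 0.14, and NKD1, an inhibitor and target of Wnt signalling, at -0.69 ± 0.26. None of these 6 genes passed the adjusted threshold. FEZF2 had a mean log2 signal of 5.53 with DMSO and 4.87 with TBBD, POTEC 5.35 and 6.26, and PALM2AKAP2 5.57 and 4.54. Olfactory receptor genes, not expected to be expressed in these cells, had a median level of 5.40. Whether FEZF2, POTEC and PALM2AKAP2 were expressed is therefore uncertain. With the median over probesets in place of their mean, FEZF2 stood at -0.22, PIM2 at -0.25 and NKD1 at -0.43, and without DMSO replicate 1 LOX stood at 0.44 and NKD1 at -0.32.

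With limma, 0 of 18640 genes had an adjusted p under 0.05 and 0 had one under 0.1, the smallest adjusted p being 1. At an unadjusted p under 0.05 there were 139 genes, 74 higher and 65 lower with TBBD, where chance alone gives 932. The relaxed criterion, an unadjusted p under 0.05 with a fold of at least 1.5, held 20 genes, 10 in each direction. The smallest unadjusted p of limma was 0.000774, for POTEC. Both TBBD arrays lay on 1 side of both DMSO arrays for 3888 genes, or 20.9%, where chance gives 33.3%. The median standard error of a gene's log2 difference was 0.14 and the median half-width of its 95% confidence interval was 0.36. In this fit a smaller difference was not detectable for the typical gene even before adjustment. The spread in this fit also holds the difference between replicates 1 and 2, which the group term alone does not remove. With the replicate number as a block, limma gave 496 genes at an unadjusted p under 0.05, still below the 932 of chance.

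Of the 20 genes of the relaxed criterion, 9 higher and 9 lower with TBBD met the naming rule. Besides POTEC and LOX, the higher ones were NPHS1, the nephrin gene of the kidney filter, at a log2 difference of 0.82 ± 0.15 (SE), AK3L1 at 0.66 ± 0.22, the mitochondrial carrier gene SLC25A47 at 0.62 ± 0.13, the diacylglycerol kinase gene DGKI at 0.60 ± 0.23, the ubiquitin ligase gene RNF5 at 0.60 ± 0.23, ABHD16B at 0.59 ± 0.11 and GPR89B at 0.59 ± 0.12. Besides PALM2AKAP2, FEZF2, PIM2 and NKD1, the lower ones were POM121C, a nuclear pore gene, at -0.77 ± 0.12, LRRC37A at -0.64 ± 0.21, NKAIN1 at -0.63 ± 0.20, the zinc finger gene ZNF583 at -0.60 ± 0.21 and the small nucleolar RNA gene SNORD74 at -0.59 ± 0.12. POTEC, NPHS1, GPR89B, PALM2AKAP2, POM121C, LRRC37A and SNORD74 rested on 1 probeset each. POTEC, GPR89B, POM121C and LRRC37A also have near-identical copies in the genome, so their values are uncertain. Mean log2 signals with DMSO were 4.56 for DGKI, 4.90 for ABHD16B and 5.44 for SLC25A47, near or below the olfactory receptor median of 5.40. With the median over probesets AK3L1 stood at 0.16 and SLC25A47 at 0.17. AK3L1 is an older symbol that matched 2 current adenylate kinase genes, and its name was kept.

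**Figure D1:**
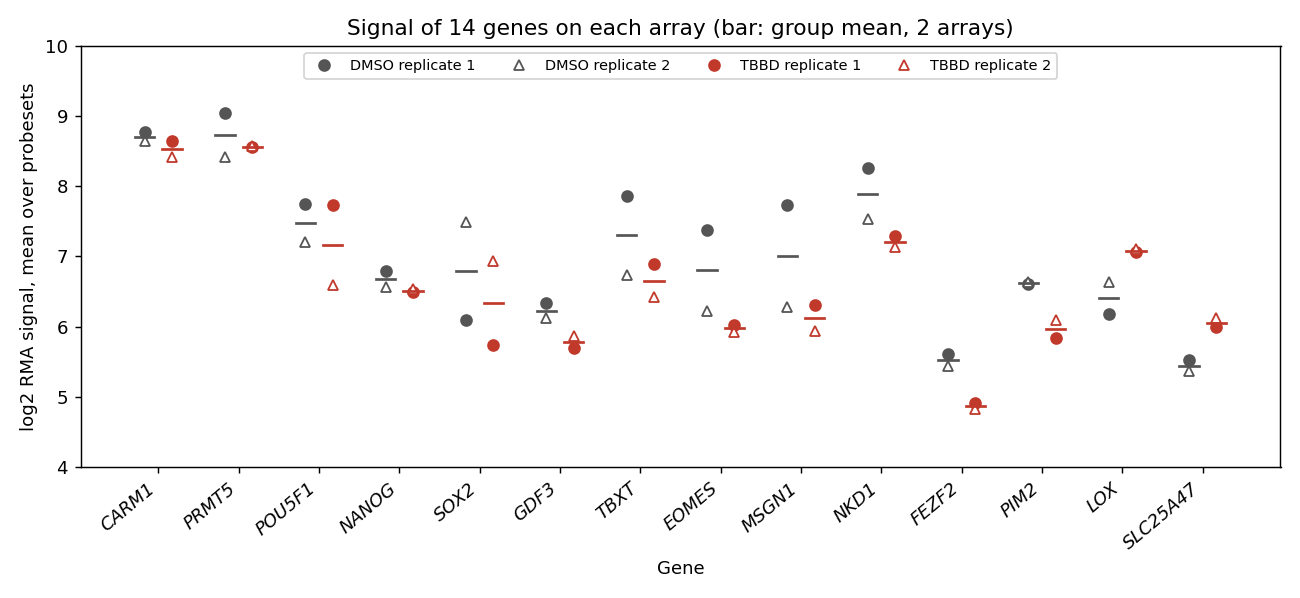
Log2 RMA signal, averaged over the probesets of each gene, on the 2 DMSO arrays (grey) and the 2 TBBD arrays (red), with replicate 1 as filled circles, replicate 2 as open triangles and bars at group means. FEZF2, PIM2 and LOX were named by a rule that asks for both TBBD values on 1 side of both DMSO values, while for SOX2 and POU5F1 the replicates of a group stand further apart than the group means.

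CARM1 itself had a log2 signal of 8.71 ± 0.08 (SD, n = 2) with DMSO and 8.53 ± 0.15 (SD, n = 2) with TBBD. Its difference was -0.18, with a 95% confidence interval from -0.52 to 0.17, and it did not pass the test. Leaving out 1 array moved it between -0.29, without TBBD replicate 1, and -0.066, without TBBD replicate 2, and it was -0.12 without DMSO replicate 1. The related methyltransferase genes PRMT1 at -0.12 ± 0.17 (SE), PRMT5 at -0.16 ± 0.23 and PRMT6 at 0.13 ± 0.14 did not pass either. In the list of the arginine methyltransferase family, 8 of 12 measured members lay lower with TBBD, with a median of -0.13, and the list was not called by camera (adjusted p = 0.246). The list of CARM1 partner coactivators had 6 of 12 members lower and 6 higher, a median of -0.00084, and was not called either (camera adjusted p = 0.700). In both lists 0 members had an adjusted p under 0.05 in limma over all genes, and 0 had one adjusted over the list alone.

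Core pluripotency genes lay lower with TBBD as a group. The median log2 difference of the 27 measured members was -0.18, and 25 were lower and 2 higher. GDF3, a TGF-beta family ligand of undifferentiated cells, differed by -0.45 ± 0.14 (SE), LIN28B, which blocks maturation of let-7 microRNAs, by -0.31 ± 0.14, and SFRP2, a secreted Wnt modulator, by -0.38 ± 0.19. The core transcription factor genes differed by -0.31 ± 0.41 for POU5F1, -0.17 ± 0.13 for NANOG and -0.46 ± 0.59 for SOX2. Against the DMSO array of the same number, SOX2 stood at -0.35 in replicate 1 and -0.56 in replicate 2. In the same order POU5F1 stood at -0.012 and -0.60 and NANOG at -0.30 and -0.031. The standard error of SOX2 also holds a difference of 1.29 between the replicate numbers. Of the hepatic and visceral endoderm markers 16 of 18 lay higher with TBBD, and of the mesenchyme and matrix markers 17 of 22, and camera called neither list (adjusted p = 0.430 and 0.318).

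The pluripotency list was called by camera (adjusted p = 8.6e-05), and the call was lost with an estimated correlation between members (adjusted p = 0.982 with an estimated correlation). That setting called 0 of the 51 lists and could call little with 2 arrays a group. A call lost under it therefore decides nothing, for this list or the lists below. Over all genes 0 members had an adjusted p under 0.05 in limma, and adjusted over the list alone 0 had one. The list's median was -0.22 in replicate 1 and -0.21 in replicate 2, where TBBD is set against the DMSO array of the same number, and 14 of the 27 members were lower in both. The median was -0.0047 without DMSO replicate 1 and -0.07 without TBBD replicate 2, against -0.35 without DMSO replicate 2 and -0.33 without TBBD replicate 1. Those fits leave the replicate numbers unequal, and this list was lower on the replicate 2 arrays, at a median of -0.28. NANOG stood at -0.051 and SFRP2 at -0.18 without DMSO replicate 1, and LIN28B at -0.20 without TBBD replicate 2. The median signal of the list was 7.07 on DMSO 1, 7.04 on DMSO 2, 7.25 on TBBD 1 and 6.65 on TBBD 2. Yet 21 of 27 members were lower on TBBD 1 than on DMSO 1, so this median over genes of unlike level does not rank the arrays.

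Primitive streak and early mesoderm genes, which mark the first step of germ layer formation, showed the largest shift of any called list. Their median log2 difference was -0.36 over 18 measured members, 17 of them lower. EOMES, a T-box factor of mesendoderm, differed by -0.83 ± 0.38 (SE), MSGN1, a regulator of presomitic mesoderm measured on 1 probeset, by -0.89 ± 0.48, MESP1, a regulator of early cardiac mesoderm, by -0.39 ± 0.18 and TBXT, which encodes brachyury, by -0.65 ± 0.40. In replicate 1 all 18 members were lower and the median was -0.67, whereas in replicate 2 the median was 0.05, with 8 members lower and 10 higher.

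The streak list was called by camera (adjusted p = 9.5e-06), and the call was lost with an estimated correlation (adjusted p = 0.982 with an estimated correlation). In limma 0 members had an adjusted p under 0.05 over all genes and 0 adjusted over the list alone. The median was -0.0030 without DMSO replicate 1 (camera adjusted p = 0.642) and -0.81 without DMSO replicate 2. In the same order EOMES stood at -0.25 and -1.40, MSGN1 at -0.16 and -1.61, TBXT at -0.085 and -1.22, and MESP1 at -0.17 and -0.60. Those fits leave the replicate numbers unequal, and the streak list was lower on the replicate 2 arrays, at a median of -0.48.

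Genes of G2/M and mitosis lay slightly lower with TBBD, with a median log2 difference of -0.09 over 29 measured members, 25 lower and 4 higher. The mitotic kinase gene AURKA differed by -0.31 ± 0.16 (SE), and CDCA8 and BIRC5, of the chromosomal passenger complex, by -0.23 ± 0.15 and -0.15 ± 0.12. Camera called the list (adjusted p = 0.033), and the call was lost with an estimated correlation (adjusted p = 0.982 with an estimated correlation). In limma 0 members had an adjusted p under 0.05 over all genes and 0 adjusted over the list alone. The direction turned without DMSO replicate 1, to 0.088, and without TBBD replicate 2, to 0.055. The median was -0.28 without DMSO replicate 2 and -0.29 without TBBD replicate 1. Those fits leave the replicate numbers unequal, and these genes were lower on the replicate 2 arrays, at a median of -0.36. Against the DMSO array of the same number, the median was -0.12 in replicate 1 and -0.097 in replicate 2. Of the 29 members, 18 were lower in both. Camera's call ended with the dimmer genes left out down to the brightest 9320 (adjusted p = 0.0514) and with the median over probesets (adjusted p = 0.122).

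Olfactory receptor genes, listed as genes not expected to be expressed in these cells, lay higher by a median of 0.03 on the log2 scale over 348 measured members, 220 higher and 128 lower. OR5M11 differed by 0.45 ± 0.11 (SE), OR6F1 by 0.43 ± 0.11 and OR51S1 by 0.41 ± 0.14, each on 1 probeset. Camera called the list (adjusted p = 0.00557), and the call was lost with an estimated correlation (adjusted p = 0.982 with an estimated correlation). In limma 0 members had an adjusted p under 0.05 over all genes and 0 adjusted over the list alone. The list's median lay inside the middle 95% of 10000 random lists matched on level, which ran from 0.0048 to 0.030, and the median of the dimmest 3728 of all genes was 0.018. The call ended without DMSO replicate 2 (adjusted p = 0.101), without TBBD replicate 1 (median 0.05, adjusted p = 0.103) and among genes with at least 3 probesets (adjusted p = 0.333).

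The other 47 lists were not called by camera. Genes of the endoplasmic reticulum's unfolded protein response came nearest, with a median log2 difference of 0.06, 19 of 22 members higher and an adjusted p of 0.0543. Camera called this list with quantile normalization again (adjusted p = 0.0483) and on ranks (adjusted p = 0.0289), among other settings. It also did so among the brightest 12426 genes (adjusted p = 0.0038) and the brightest 9320 (adjusted p = 0.0061). The call was not made with an estimated correlation (adjusted p = 0.982 with an estimated correlation). Wnt targets had a median of -0.12 (camera adjusted p = 0.125), trophoblast markers 0.15 (camera adjusted p = 0.132) and endothelial markers 0.10 (camera adjusted p = 0.154). Among the brightest 12426 genes camera called the Wnt and the endothelial lists (adjusted p = 0.0367 for each), and over all genes neither was called with an estimated correlation (adjusted p = 0.982 with an estimated correlation). With 1 array left out, camera placed the Wnt list lower without DMSO replicate 2 and the trophoblast list higher without TBBD replicate 2. The endothelial list lay higher without DMSO replicate 2 or TBBD replicate 1 but lower without TBBD replicate 2. Those fits leave the replicate numbers unequal, and endothelial markers were higher on the replicate 2 arrays by a median of 0.60. Astroglial markers had a median of 0.04, with 14 of 21 members higher (camera adjusted p = 0.683). Within that list GFAP differed by 0.07 ± 0.20 (SE), S100B by -0.15 ± 0.15, which was -0.0020 without DMSO replicate 2, and NFIA by -0.06 ± 0.12. Targets of p53 had a median of -0.01, and CDKN1A differed by 0.04 ± 0.20. Markers of definitive endoderm had a median of -0.05, and SOX17 differed by -0.29 ± 0.26. Neural progenitor markers had a median of -0.04, and PAX6 differed by 0.20 ± 0.17 and by 0.016 without TBBD replicate 2. With DMSO, GFAP at a mean log2 signal of 5.67, S100B at 5.32 and PAX6 at 5.34 lay near the olfactory receptor median level of 5.40. Hepatic and visceral endoderm markers had a median of 0.12, with 10 members higher in both replicates, and AFP at 0.29 ± 1.09. AFP stood at 0.35 in replicate 1 and 0.24 in replicate 2, and its standard error also holds a difference of 2.43 between the numbers. Mesenchyme and matrix markers had a median of 0.10, with 14 members higher in both replicates. Both lists lay lower without DMSO replicate 1 and higher without DMSO replicate 2 or TBBD replicate 1, and mesenchyme markers lower without TBBD replicate 2. With 1 array left out the replicate numbers are unequal. Both lists were higher on the replicate 2 arrays, by medians of 0.85 and 1.12. These directions follow the number left in excess and are not read as responses to TBBD. The microRNA host gene MIR17HG differed by 0.02 ± 0.18. In each of these lists 0 members had an adjusted p under 0.05 in limma over all genes, and 0 had one adjusted over the list alone.

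**Figure D2:**
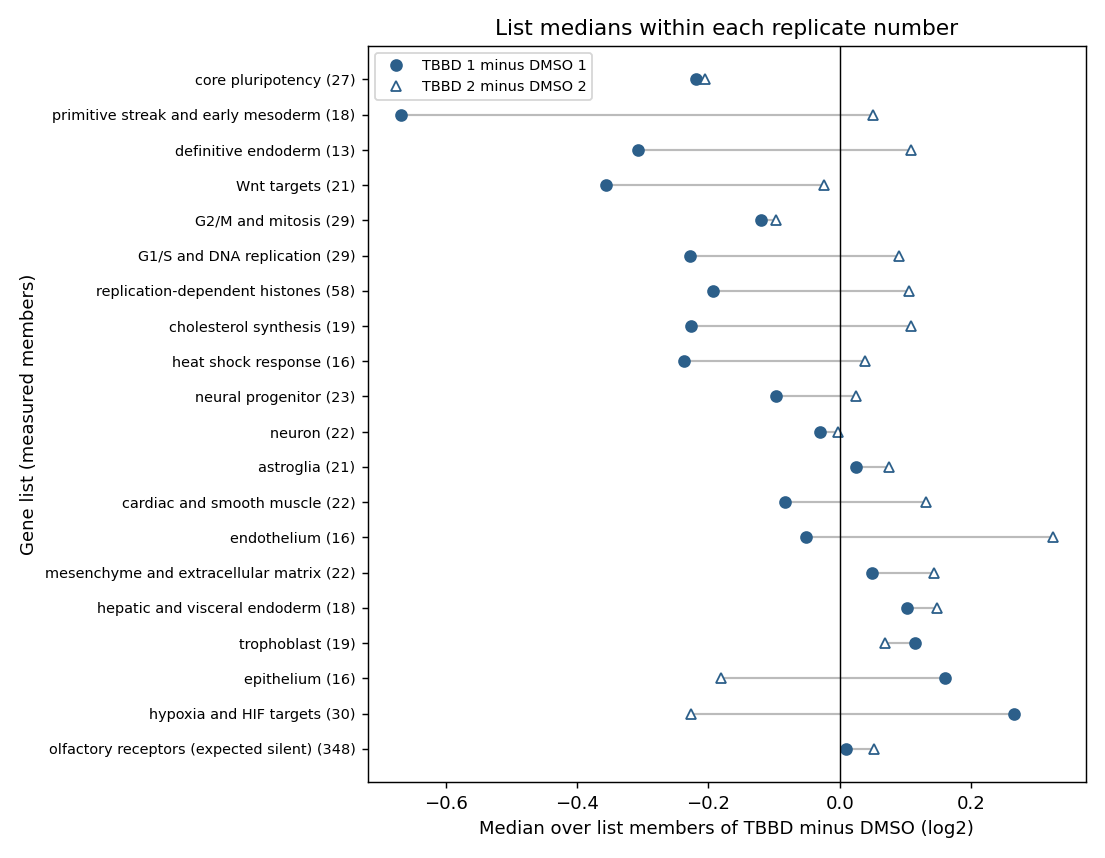
Median log2 difference between TBBD and DMSO over the measured members of 20 gene lists (numbers of members in brackets), for replicate 1 as filled circles and replicate 2 as open triangles. Core pluripotency genes lie at -0.22 and -0.21, whereas primitive streak genes lie at -0.67 in replicate 1 and 0.05 in replicate 2.

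The differences in replicate 1 and in replicate 2 did not resemble each other. Across the 18640 genes, which are not independent replicates, TBBD 1 minus DMSO 1 and TBBD 2 minus DMSO 2 had a Pearson correlation of -0.152 and a Spearman correlation of -0.147, and 44.5% of genes had the same sign in both. With no shared effect the correlation would lie near 0, since the 2 differences share no array. With the TBBD arrays exchanged the correlation was -0.666. Arrays of 1 treatment stood further apart than arrays of 1 number. The SD across genes was 0.31 for DMSO 2 minus DMSO 1 and 0.33 for TBBD 2 minus TBBD 1, against 0.21 and 0.19 for TBBD minus DMSO in replicates 1 and 2.

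**Figure D3:**
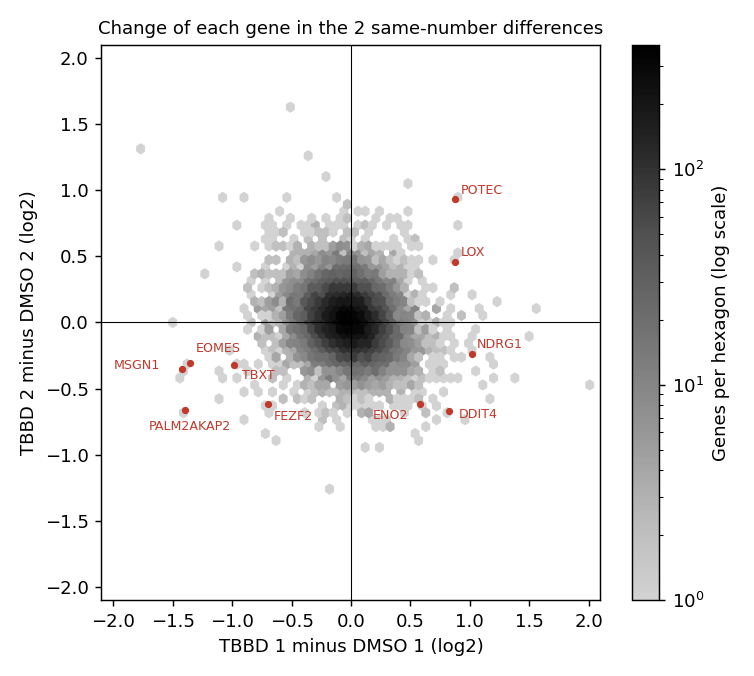
Log2 difference of each of 18640 genes in TBBD 1 minus DMSO 1 (horizontal) and TBBD 2 minus DMSO 2 (vertical), shaded by the number of genes per hexagon on a log scale, with 10 genes marked in red, of which DDIT4, NDRG1 and ENO2 were chosen after their values were seen. The cloud tilts slightly downward, with a correlation of -0.152.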

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

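The settings for the correlation of the same-number differences and the placeholder cells at 0 were chosen after seeing the data. No gene passed limma's adjusted threshold under any alternative, single probesets included (6633 of 247035 at an unadjusted p under 0.05). The relaxed count of 20 genes became 13 among the brightest 12426 genes and 9 among the brightest 9320, 11 for genes with at least 3 probesets, 45 with the median over probesets, 1 at p under 0.01 and a fold of at least 2, and 6145 on single probesets, of which far more were tested. The count was 64 and camera called 11 lists without DMSO replicate 1, 159 and 15 without DMSO replicate 2, 112 and 13 without TBBD replicate 1, and 124 and 14 without TBBD replicate 2. Leaving out an array assumes that the lone array of its group varies like the others, and made treatment and replicate number unequal by construction. The 4 called lists became 0 with an estimated correlation and 0 with fry. Estimating the correlation also left the mesenchyme list uncalled for the replicate number, where 18 of 22 members passed limma's adjusted threshold. It could therefore call little on these arrays. The labels tie the replicate numbers to no shared batch; deviations from the group means of same-numbered arrays correlated at 0.566 across genes. With the number as a block, 0 genes passed the adjusted threshold and 496 had an unadjusted p under 0.05, the relaxed count was 41, and camera called 11 lists: the 4 already called, hepatic, trophoblast, endothelial, mesenchyme and unfolded protein response genes higher, and G1/S genes and Wnt targets lower, with none called once the correlation was estimated (adjusted p = 0.983 with an estimated correlation). The correlation of the same-number differences was -0.041 on single probesets, and the cause was not tested.

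Of the values of named genes under the alternatives, 183 could have turned and 18 did; the others were fixed by construction, since the setting left the value as it was or the gene's groups were separated. The median over probesets moved 18 of the 32 named genes on at least 3 probesets by over 1.5 times, among them SOX17 to -0.047, CDCA8 to -0.060, EOMES to -0.44, PRMT1 to -0.028, CDKN1A to 0.22 and MIR17HG to 0.17, and GFAP was -0.16 and S100B 0.056. Of the separated genes, AURKA stood at -0.12, CDCA8 at -0.079, BIRC5 at -0.069, LRRC37A at -0.38 and DGKI at 0.40 without DMSO replicate 1, ZNF583 at -0.32 without TBBD replicate 1, and AK3L1 at 0.38 and RNF5 at 0.31 without TBBD replicate 2. Leaving out 1 array gave ranges of -0.30 to 0.054 for PRMT1, -0.48 to 0.15 for PRMT5, -0.013 to 0.26 for PRMT6, -0.87 to 0.26 for POU5F1, -1.16 to 0.24 for SOX2, -0.13 to 0.26 for GFAP, -0.30 to -0.0020 for S100B, 0.016 to 0.38 for PAX6, -0.14 to 0.019 for NFIA, -0.16 to 0.20 for MIR17HG, -0.19 to 0.28 for CDKN1A, -0.65 to 0.083 for SOX17 and -0.95 to 1.54 for AFP, and -0.29 to 0.088 for the median of the G2/M list. AFP, SOX2, GFAP, POU5F1, PRMT1 and the G2/M list kept 1 sign in both same-number differences. Their reversals here followed the unequal numbers. The cause of the others was not tested. No background estimate was used here, so it is unknown which genes lay above background, and no limit from signal over background was set.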

Other observations

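The tests of explanations, the comparisons with random lists and the tests of the replicate number in this part were chosen after the results they bear on had been seen, while leaving out each array was planned. The replicate number separated the arrays far more than the treatment did. With the treatment in limma's model, 653 genes differed between the numbers at an adjusted p under 0.05, 428 higher and 225 lower in number 2. Splitting the arrays by number alone gave 1001 genes, the treatment split 0 and the third split 0, which points to a structure of the samples. The third split had 388 genes at an unadjusted p under 0.05 in limma, below the 932 that chance alone gives. Genes higher in number 2 included DLK1, an imprinted Notch-family ligand gene, by 3.93 on the log2 scale, the matrix genes DCN by 3.21 and MFAP4 by 2.84, the glycoprotein hormone subunit gene CGA by 2.55, and the fetal liver genes AFP by 2.43 and FGB by 2.39. Genes lower in number 2 included NTS at -2.13, ATP12A at -2.03, CLDN10 at -2.01, SPP1 at -1.95 and FGF19 at -1.80.

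By list, mesenchyme and matrix markers were higher in number 2 by a median of 1.12, with 18 of 22 members past limma's adjusted threshold. Hepatic and visceral endoderm markers were higher by 0.85, with 9 of 18 members past it higher and 1 lower. Endothelial markers were higher by 0.60, with 8 of 16 past it. Primitive streak genes were lower at -0.48, with 3 of 18 members past the threshold, heat shock genes at -0.41, with 0 of 16, epithelial markers at -0.36, with 3 of 16, G2/M genes at -0.36, with 1 of 29, integrated stress response genes at -0.36, with 7 of 27, and core pluripotency genes at -0.28, with 7 of 27 lower and 1 higher. None of these lists was called for the number by camera once the correlation was estimated (adjusted p = 0.759 with an estimated correlation for each). The labels do not say what the numbers stand for.

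The first pattern weighed was the lower core pluripotency list with TBBD. Under a single deviating array, 1 of the same-number differences, which share no array, would lie near 0; the median was -0.2053 in number 2 and -0.22 in number 1, both below the middle 95% of 10000 random lists matched on level, but 21 of 51 lists lay outside that range in number 1 and 18 in number 2, so that range excludes nothing here. TBBD 2 had the lowest and TBBD 1 the highest median signal of the list. Yet 21 of 27 members were lower on TBBD 1 than on DMSO 1, so that median does not rank the arrays. The difference was -0.0047 without DMSO 1 and -0.07 without TBBD 2, both of which leave the numbers unequal. With the trend of the TBBD difference on the number difference over all genes removed (slope 0.0846), the median was -0.1452. So this average trend did not carry the whole difference. As the whole cause it would need a slope of 0.652. The slope fitted across the other 50 lists, which were resampled, had a middle 95% of 0.0766 to 0.263. That range is the uncertainty of an average slope and not the spread of single lists. It does not decide whether this list followed the number more steeply. Single arrays, such a steeper shift, a response to TBBD and a difference between cultures in the share of undifferentiated cells all stay open.

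The second pattern was the lower primitive streak list with TBBD. The median signal of the list was 7.05 on DMSO 1, against 6.14 on DMSO 2, 6.26 on TBBD 1 and 6.01 on TBBD 2, and in number 2 the difference was 0.05018, inside the middle 95% of matched random lists. A high level in DMSO replicate 1 alone may therefore account for the call. In number 2 EOMES was still lower at -0.30, MSGN1 at -0.35, TBXT at -0.32 and MESP1 at -0.11. In that difference 10 of the 18 members were higher. EOMES, MSGN1 and MESP1 were named for their small p, so they do not stand for the list. Removing the trend on the number left a median of -0.3097. As the whole cause the trend would need a slope of 0.752. The slope fitted across the other 50 lists had a middle 95% of 0.0736 to 0.179. That range too is for an average slope, so it leaves open whether this list followed the number more steeply. Whether DMSO 1 stood at another moment of a brief streak stage, or TBBD acted in 1 culture only, was not tested.

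The third pattern was that the same-number differences ran against each other. Noise of dim genes would weaken the relation in bright genes, but the correlation was -0.2923 in the brightest 3728 genes and -0.068 in the dimmest 3728. Quantile normalization again left the correlation over all genes at -0.1486. The array medians already lay between 6.39 and 6.42, so normalizing again could change little and does not test the scaling of the arrays. Of 51 lists, 18 differed between the 2 differences by more than the middle 95% of matched random lists, where chance gives 2.55 for independent genes, and of those outside in both differences 9 lay on opposite sides of 0 and 2 on the same side. Targets of the hypoxia-inducible factor had medians of 0.26 in number 1 and -0.23 in number 2, a gap of 0.4943, with DDIT4 at 0.83 and -0.67, NDRG1 at 1.02 and -0.24, and ENO2 at 0.58 and -0.62. The list was picked for this gap, so the gap tests nothing, and no biological explanation was tested.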
